A study of Homo sapiens with 2 samples.

How the data were processed

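RNA from 2 cultures was measured on Illumina bead arrays, with 1 array per culture. HCT-8 is an established human colon cancer cell line, and HCT-8/V is its vincristine-resistant counterpart. Per the labels, both were grown in RPMI medium with fetal bovine serum, and both had been transferred with a plasmid carrying Twist (pcDNA3.1-Twist) 48 h before RNA was taken. Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled cRNA was made with a MessageAmp kit for Illumina arrays. No array of cells without the plasmid was analysed here, so cell line was the only contrast that the labels give between the arrays. Both carry the same treatment text, and the labels do not settle whether 1 of them was meant as an untreated control. Neither the effect of the plasmid nor an interaction with resistance could therefore be estimated.

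The deposited table held 1 intensity per probe and array, on a linear scale, for 47323 probes. How the authors corrected the background and scaled the arrays was not given in the sources used here. From the values themselves, the intensities were already background-subtracted and matched in distribution. On both arrays the minimum was -44.98, the 75th percentile 81.3 and the maximum 19759, and 29.2% of probes were below 0. The medians were 12.44 for HCT-8 and 12.42 for HCT-8/V. The table gave no detection p-values. Because the distributions had been matched before deposit, a change in total RNA per cell or a shift of most genes in one direction would not be visible.

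Gene names came from the platform annotation given with the table, which can be old. Of the probes, 30113 had 1 gene symbol, 8 had several and 17202 had none, and the 17210 without a single symbol were left out of all gene results. Through the Entrez gene ID, 30074 probes were matched to the RefSeq gene table of assembly GRCh38.p14, which was used only for current names and for the order of neighbouring genes, and 39 were not matched and kept the symbol of the annotation. This gave 20046 genes, of which 6691 had several probes. The brightest probe by mean intensity stood for each gene.

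Values were floored at each array's median over all probes and then taken to log2. A gene counted as expressed when it was above the floor on at least 1 array. Differences are HCT-8/V minus HCT-8 throughout. Where only 1 array was above the floor, the fold is a lower bound against the floor and is written as "at least", and no fold was given where neither array was above it. A difference of at least 2-fold was counted as large. A higher floor, at the 75th percentile of all probes, separated bright from dim genes. As a guide to how unusual a single difference was, it was set against the 500 expressed genes of the most similar mean brightness.

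With 1 array per line, no test of a difference was possible, no p-value is given, and there is no replicate check of any value. The number of arrays limits the precision: a difference between these arrays can come from the cell lines, from these cultures or from the arrays. All differences are described by size.

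In all, 38 gene lists covering drug transport, tubulins, drug metabolism, epithelial and mesenchymal genes, cell cycle, stress and immune pathways and markers of other cell types were fixed before the data were examined, as were the settings, the alternatives and the rule for naming genes. For each list with at least 5 expressed members, the median log2 difference of those members was set among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called apart at the 2nd percentile or less or at the 98th percentile or more, which chance gives for 4% of lists of unrelated genes. This percentile describes these arrays and is no test of the cell lines. Only 4 metallothionein genes were expressed, so 37 lists were ranked. Runs of neighbouring genes were sought as windows of 15 expressed genes along each chromosome whose median lay beyond every window of 1000 shuffles of gene order.

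By the rule, the text names TWIST1 and ABCB1, the 15 genes with the largest difference in each direction among those above the floor on both arrays, the 5 brightest genes above the floor on only 1 array in each direction, and the 4 members with the largest difference of each list that stood apart or that concerns drug resistance or the transferred gene. Because most of these turned out to be dim, genes past 2-fold at the higher floor, and bright members of lists, are named as well and were chosen after their values were seen.

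Noise was estimated from the spread between arrays of probes with a mean intensity below 0, and from 2 probes of the same gene. Alternatives covered quantile normalization, median centring, removal of a loess trend with brightness (span 0.3), the higher floor, no floor (log2 of the intensity plus 46.0), the mean over all probes of a gene, fold thresholds of 3 and 1.5, agreement of several probes, all measured list members, the mean of a list in place of its median, and windows of 25 genes. The procedure was tested on simulated data made from this table with 200 changed genes. For the HCT-8/V against HCT-8 comparison over 20046 genes, 54 of 64 genes changed 4-fold and lying above the higher floor passed 2-fold, 55 of 55 genes changed 2-fold had the right sign, a list shifted 1.3-fold ranked at percentile 100, and a run of 30 genes shifted 3-fold was found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.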

Results

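Gene expression was profiled in 2 cultures, labelled HCT-8, a human colon cancer line, and HCT-8/V, 48 h after transfer of a plasmid carrying Twist. Their identity was not checked against a reference profile. TWIST1 is a transcription factor of mesoderm development that is widely used to drive epithelial-mesenchymal transition, the change of epithelial cells towards a mobile, mesenchymal state. HCT-8 is the parental line and HCT-8/V is its derivative resistant to vincristine, a vinca alkaloid that binds tubulin and blocks the mitotic spindle. Each line was measured on 1 array with no replicate. The labels give both samples the same treatment, and if either was in fact an untreated control, every difference would include the effect of the plasmid. Of 20046 named genes, 13763 (68.7%) were above the floor on at least 1 array and 11356 on both. The comparison asks which genes, drug resistance genes among them, differed between resistant and parental cells when both carried the plasmid.

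TWIST1 was measured above both floors in both lines. Its single probe read 163 in HCT-8 and 185 in HCT-8/V, a log2 difference of 0.19, and 64% of genes of similar brightness differed by as much. Whether that probe lies in the transferred coding sequence was not checked, so it may read the endogenous transcript alone or both. The related gene TWIST2 read 290 in HCT-8 and 212 in HCT-8/V.

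ABCB1, which encodes P-glycoprotein, the efflux pump that exports vincristine, was dim in both lines and was not higher in the resistant one. Its brighter probe read 37.7 in HCT-8 and 11.4 in HCT-8/V, where only HCT-8 was above the floor, so the reading in HCT-8/V was at least 3.03-fold lower (log2 -1.60, or -0.80 with the mean of both probes). Of genes of similar brightness, 13% differed by as much. Its second probe was below the floor in both lines, at -0.986 in HCT-8 and 4.94 in HCT-8/V. Neither line was above the higher floor for ABCB1, and at these levels a change of direction cannot be read from a single array.

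The other ABC transporters of drug efflux were split in direction, with 6 expressed members higher and 5 lower in HCT-8/V, ABCB1 included. ABCA2, an intracellular lipid transporter, was the brightest member with a sizeable difference, at 613 in HCT-8 and 339 in HCT-8/V, a log2 difference of -0.86 that was -0.43 with the mean of its probes. ABCC3 was nearly equal, at 970 and 1002, and ABCC2 read 159 and 137. ABCC11 (19.6 and 9.78) and the bile salt pump ABCB11 (5.89 and 17.4) lay around the floor, and ABCG2 and ABCB4 were below it in both lines. Among uptake carriers, 8 were higher and 7 lower. The largest differences there were all in dim genes, with the organic cation transporter SLC22A2 at least 2.97-fold lower, SLCO1B1 at least 1.73-fold higher (with the mean of all probes, log2 -0.79 for SLC22A2 and 0.40 for SLCO1B1), and the copper exporter ATP7B and SLCO2B1 at 1.60-fold and 1.51-fold higher. For ATP7B and SLCO2B1 the mean of all probes turned the direction, to log2 differences of -0.30 and -0.16. The chromosomal neighbours of ABCB1 on 7q21, which are often co-amplified in resistant lines, were not higher together: with ABCB1 itself counted, 12 were higher and 13 lower. CDK14 read 37.3 in HCT-8 and 11.1 in HCT-8/V, while STEAP4 was at least 2.71-fold and GTPBP10 1.78-fold higher. No list of drug transport genes stood apart from random lists, with efflux transporters at percentile 52.4, uptake carriers at 66.4 and the neighbours of ABCB1 at 29.5. At the higher floor 5 of the neighbours were higher and 9 lower (percentile 4.68), and again no such list stood apart.

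Tubulin genes, which encode the target of vincristine, were evenly split, with 9 of 18 higher. TUBB3, the neuronal beta-tubulin linked to resistance to microtubule drugs, read 141 in HCT-8 and 234 in HCT-8/V, a log2 difference of 0.74. TUBA4A was also higher (623 and 914), TUBB6 was lower (578 and 404), and TUBB1 was dim (17.3 and 2.60). Of 32 microtubule regulators, 14 were higher and 18 lower. The brightest probe of MAPT, which encodes tau, was 1.72-fold higher and that of MAP2 at least 1.60-fold higher, but the mean of all probes turned both directions, to log2 differences of -0.21 and -0.10. The plus-end binding gene CLASP2 was 1.70-fold lower and MAP1S was 1.47-fold lower. The tubulins ranked at percentile 66.4 and the regulators at 23.2. At the higher floor they ranked at 94.2 and 28.3, and neither list stood apart.

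Genes of drug metabolism, antioxidant defence and cell death were mixed. In phase I metabolism 20 were higher and 12 lower, with the carbonyl reductase CBR1 at 95.7 in HCT-8 and 180 in HCT-8/V, ALDH3B1 at 301 and 514 (a log2 difference of 0.77, but 0.02 with the mean of its probes), CYP2C8 at least 2.04-fold higher and CES1 at least 1.83-fold lower. In phase II metabolism 12 were higher and 12 lower. TPMT, which methylates thiopurines, read 204 and 373, UGT8 was 1.70-fold higher, UGT1A6 at least 1.65-fold higher and UGT2A3 at least 2.18-fold lower (log2 -0.56 with the mean of all probes). NRF2 targets were split 13 to 13, with HMOX1 at 67.4 and 123, the cystine transporter SLC7A11 at 33.7 and 47.6, and ME1 at 824 and 606. Pro-apoptotic genes were more often higher (21 of 33) and anti-apoptotic genes more often lower (13 of 19). Among the former, HRK was 1.84-fold, and the dim BIK and BAK1 1.69-fold and 1.68-fold higher, while DAPK1 was 1.78-fold lower. Among the latter, the caspase inhibitor gene BIRC2 read 808 and 444, while the dim XIAP (32.0 and 13.9) was 2.31-fold lower and the dim TNFRSF10D and AVEN at least 2.88-fold and 1.92-fold lower. Of genes of similar brightness, 41.2% differed by as much as XIAP, 36.6% as much as AVEN and 47.2% as much as BAK1. None of these lists stood apart, at percentiles 58.6 (phase I), 47.6 (phase II), 41.4 (NRF2), 95.5 (pro-apoptotic) and 9.80 (anti-apoptotic), except that anti-apoptotic genes did as a mean in place of a median (-0.30). At the higher floor both apoptosis lists were split more evenly. There 13 of 23 pro-apoptotic genes were higher (percentile 62.6) and 6 of 11 anti-apoptotic genes lower (mean -0.06, percentile 35.6).

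Epithelial and mesenchymal genes went in both directions. Of 25 expressed epithelial genes 10 were higher and 15 lower in HCT-8/V, and of 40 mesenchymal genes 18 were higher and 22 lower. Both cultures had high levels of VIM (5921 in HCT-8 and 5944 in HCT-8/V) and S100A4 (10182 and 9932) together with the desmosomal gene JUP (4812 and 4316) and KRT8 (2199 and 2283). In both, the E-cadherin gene CDH1 was below 0 (-4.56 and -15.3). KRT7 was 1.64-fold and ERBB3 1.65-fold higher, ST14 was 1.94-fold higher, and the epithelial transcription factor EHF was at least 4.41-fold lower but dim. Among mesenchymal genes CCN1, a secreted matrix protein, was bright and 2.33-fold lower, while the dim POSTN and COL6A2 were at least 3.12-fold and 2.79-fold higher and PRRX1 was at least 2.34-fold lower. With the mean of all probes these log2 differences were 0.47, 0.49 and -0.62, all under 2-fold. Reported TWIST1 targets were split 10 to 10. They include POSTN, PDGFRA (2.11-fold lower, log2 -0.54 with the mean of all probes), the chemokine gene CCL2 (1.84-fold lower) and CDKN2A (1.59-fold higher). The percentiles were 29.8 for epithelial genes, 8.71 for mesenchymal genes and 44.9 for TWIST1 targets. The TWIST1 list was not sorted into activated and repressed genes, so its split and percentile do not test TWIST1 activity. Epithelial genes did stand apart with the mean of all probes, at a median of -0.21, and mesenchymal genes reached percentile 2.33 at the higher floor.

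Over all genes, 583 were at least 2-fold higher and 519 at least 2-fold lower in HCT-8/V, together 8.01% of the expressed genes. Most were dim: for 974 of the 1102 (88.4%) the brighter value was below the higher floor, and 587 were above the floor on only 1 array. At the higher floor 24 genes were at least 2-fold higher and 25 lower, or 0.612% of 8009 genes, where the standard deviation of the log2 differences was 0.34 and their correlation across genes, which are not independent replicates, was 0.979 (Pearson, log2). Values below the higher floor were raised to it, so a gene only little above it could not reach 2-fold. The closeness of bright genes is thus partly built in by that floor.

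**Figure D1:**
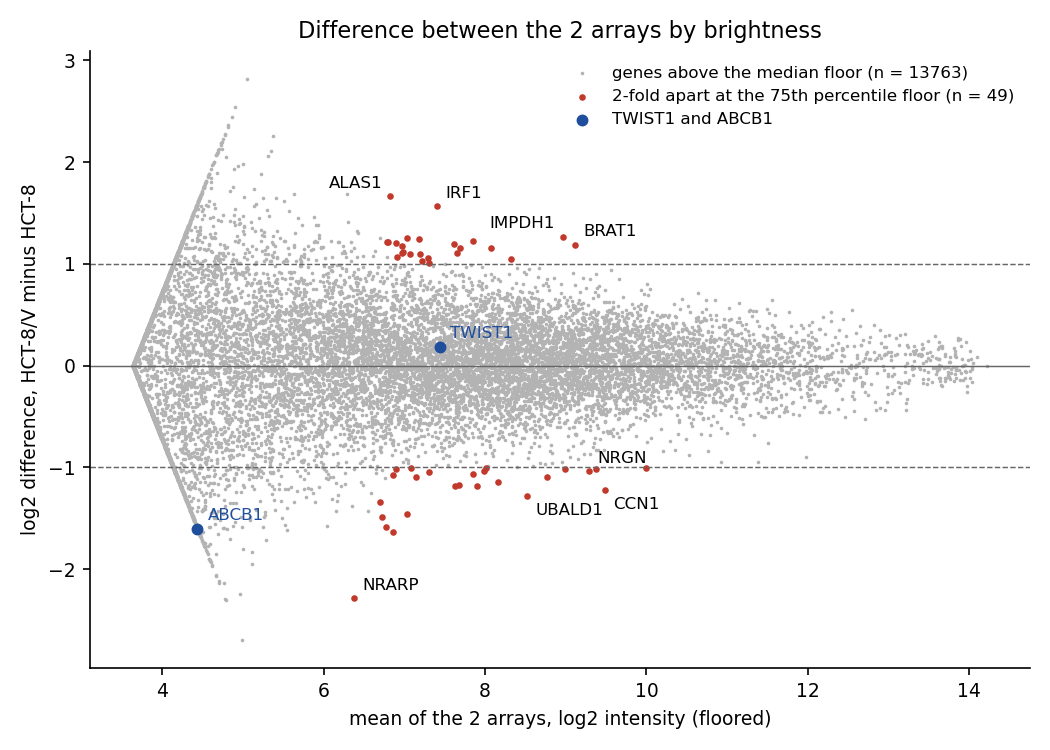
The log2 difference in intensity, HCT-8/V minus HCT-8, is plotted against the mean log2 intensity of both arrays for the 13763 genes above the floor, 1 point per gene, with dashed lines at 2-fold. The 49 genes past 2-fold at the higher floor are red, TWIST1 and ABCB1 are blue, and the diagonal edges on the left are genes at the floor on 1 array.

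The bright genes that were higher in HCT-8/V were of varied function. IRF1, a transcription factor of the interferon response, read 98.4 in HCT-8 and 292 in HCT-8/V (2.97-fold). ALAS1, the first enzyme of heme synthesis, read 63.8 and 202, IMPDH1 of guanine nucleotide synthesis 323 and 776, BRAT1 of the DNA damage response 367 and 836, and the mitochondrial dicarboxylate carrier gene SLC25A10 129 and 296. The kinase gene RPS6KA1 (2.34-fold), the base excision repair scaffold XRCC1 (2.13-fold), the proteoglycan gene CSPG4 (2.08-fold) and HRAS (2.02-fold) were also higher. The remaining higher genes were SLX9, TBC1D16, DNMT3L, STX4, MILIP, SLC25A22, ARHGEF19, RNF220, UNC119, SUPV3L1, MRTO4, LIMS2, DEF8, ZNF408 and COTL1.

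Among bright genes that were lower in HCT-8/V, CCN1 read 1093 in HCT-8 and 469 in HCT-8/V, and the calcineurin regulator RCAN1 945 and 469. NRARP, a feedback inhibitor of Notch signalling, was 4.86-fold lower (183 and 37.7) and RBPJ, the DNA-binding partner of Notch, read 191 and 95.4. The zinc finger gene MAZ was 2.75-fold, SBNO2 3.11-fold, ATXN2L 2.99-fold and UBALD1 2.43-fold lower. SAV1 of the Hippo pathway was 2.27-fold lower, the hyaluronan-binding TNFAIP6 2.25-fold, the adhesion gene L1CAM 2.20-fold and the cytokine receptor kinase JAK1 2.05-fold. The remaining lower genes were SSBP3, NAPG, INO80E, LIN7C, ZNF195, MEF2A, MAFG, NRGN, DDX17, RGPD8, TIMP3, CDC42BPB and LOC644936. All these values are from the brightest probe. Over the bright genes of both directions, a second probe went the same way in 9 of 15. Of the bright genes, only UNC119, NRARP, RCAN1 and MAFG had 2 or more probes all past 2-fold.

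The largest differences among genes above the floor on both arrays were nearly all in dim genes. Higher in HCT-8/V were DOCK3 (18.99 in HCT-8 and 90.5 in HCT-8/V, 4.77-fold), SH2D5, the p53 target RPRM, CPTP, ARHGAP10, ST3GAL2, DENND2C, SCARNA16, PPBP, NUMBL, SIT1, TTLL3, C3orf18, CRYL1 and RBM20, down to 3.34-fold for the last. Lower were NRARP, the netrin receptor gene UNC5B (67.6 and 14.2, 4.75-fold), CHD3, AKAP12, the NF-kB subunit gene REL (68.1 and 17.6, 3.87-fold), TMEM87B, NFYA, SNORD32A, FOXD4, NLRP5, SNORA22, DPT, the deacetylase gene SIRT6 (3.28-fold), SRPX and BAHD1, down to 3.15-fold for the last. Among genes above the floor in HCT-8/V alone, the brightest were FMNL1 (at least 7.05-fold higher), ADORA1 (at least 5.80-fold), EPPK1, ENTREP2 and AFG3L1P. In HCT-8 alone they were XCR1 (at least 6.46-fold lower in HCT-8/V), MUC12 (at least 4.93-fold), NOC2LP2, EHF and KRTAP10-10. Of these genes, SH2D5, DENND2C, AKAP12, REL, NFYA, FOXD4, NLRP5, ADORA1, AFG3L1P, XCR1 and KRTAP10-10 fell under 2-fold with the mean of all probes, for example to log2 differences of 0.41 for SH2D5, -0.30 for AKAP12, 0.63 for ADORA1 and -0.90 for XCR1. Of all these genes, only DOCK3, RPRM, FMNL1 and NRARP were above the higher floor on any array, and at that floor the differences were at least 1.11-fold, 1.04-fold and 1.08-fold for DOCK3, RPRM and FMNL1 and at least 2.25-fold for NRARP.

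Of 37 ranked lists, 5 stood apart from random lists, where chance gives 1.48 for lists of unrelated genes. Members of a list can vary together and some belong to several lists, so the 5 are not shown to exceed chance. Interferon response genes were the highest, with a median log2 difference of 0.34 (percentile 99.94) and 25 of 37 expressed members higher in HCT-8/V. IFIT3 and IFI44L were at least 3.22-fold and 2.57-fold higher but dim, with log2 differences of 0.74 and 0.68 with the mean of all probes, and USP18, a brake on interferon signalling, was at least 3.08-fold lower and dim. Bright members included IRF1, IFI6 (413 in HCT-8 and 644 in HCT-8/V), IRF7 (131 and 194) and the peptide transporter gene TAP1 (1327 and 1728), while OAS3 was lower (414 and 265). At the higher floor 17 of 22 members were higher, with a median of 0.32 (percentile 99.98). HLA class I presentation genes, which interferon also induces, did not share this difference (6 of 16 higher, percentile 12.9).

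Of the cell cycle lists, G2/M and mitosis genes had a median of -0.13 (percentile 0.08), with 36 of 55 lower in HCT-8/V. UBE2S (1.81-fold lower), the proliferation marker MKI67 (68.8 in HCT-8 and 38.4 in HCT-8/V), the kinetochore gene NUF2 (367 and 222), the cytokinesis gene ANLN (1359 and 828) and the spindle gene TPX2 (924 and 584) were lower, while CDC20 was higher (1375 and 1978). G1/S and DNA replication genes had a median of 0.16 (percentile 99.01), with 30 of 43 higher. CCNE1, encoding cyclin E1, read 153 and 259 on its brightest probe, and the polymerase subunit genes POLD1 and POLA2 were 1.49-fold and 1.44-fold higher. RRM2, a subunit of ribonucleotide reductase, went the other way (236 and 132). With the mean of all probes the log2 differences of CCNE1 and NUF2 shrank from 0.75 to 0.06 and from -0.72 to -0.12. No member of either cell cycle list differed by 2-fold. With the second brightest probes, an alternative chosen after seeing the data, the G1/S median was reversed and stood apart on the low side, at -0.45 over 17 genes (percentile 0.09), and the G2/M median of -0.26 over 23 genes no longer stood apart (percentile 4.49). The G1/S list also fell short of standing apart with no floor, with the mean of all probes and as a mean in place of a median.

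NF-kB and inflammatory genes had a median of -0.19 (percentile 0.665), with 21 of 27 lower in HCT-8/V. Besides REL, these were the dim CXCL5 and CSF1 (at least 2.53-fold and 2.25-fold lower, but log2 -0.67 and -0.30 with the mean of all probes), CCL2 (156 in HCT-8 and 84.9 in HCT-8/V), the subunit gene RELA (214 and 124) and the prostaglandin synthase gene PTGS2 (2240 and 1401). Heat shock genes had a median of -0.13 (percentile 1.54), with 16 of 25 lower. HSPA2 (158 and 92.7), DNAJB4 (162 and 105), HSF1 (51.5 and 33.6) and the abundant chaperone genes HSPA8 (3406 and 2488) and HSP90AA1 (7574 and 6188) were lower, and CRYAB was higher (80.8 and 129). With the second brightest probes the NF-kB median was 0.15 over 8 genes, in the opposite direction but not apart (mean -0.04, percentile 88.9), and the heat shock median was -0.48 with 9 of 9 genes lower (percentile 0.80). As a mean in place of a median the heat shock list no longer stood apart (-0.10).

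**Figure D2:**
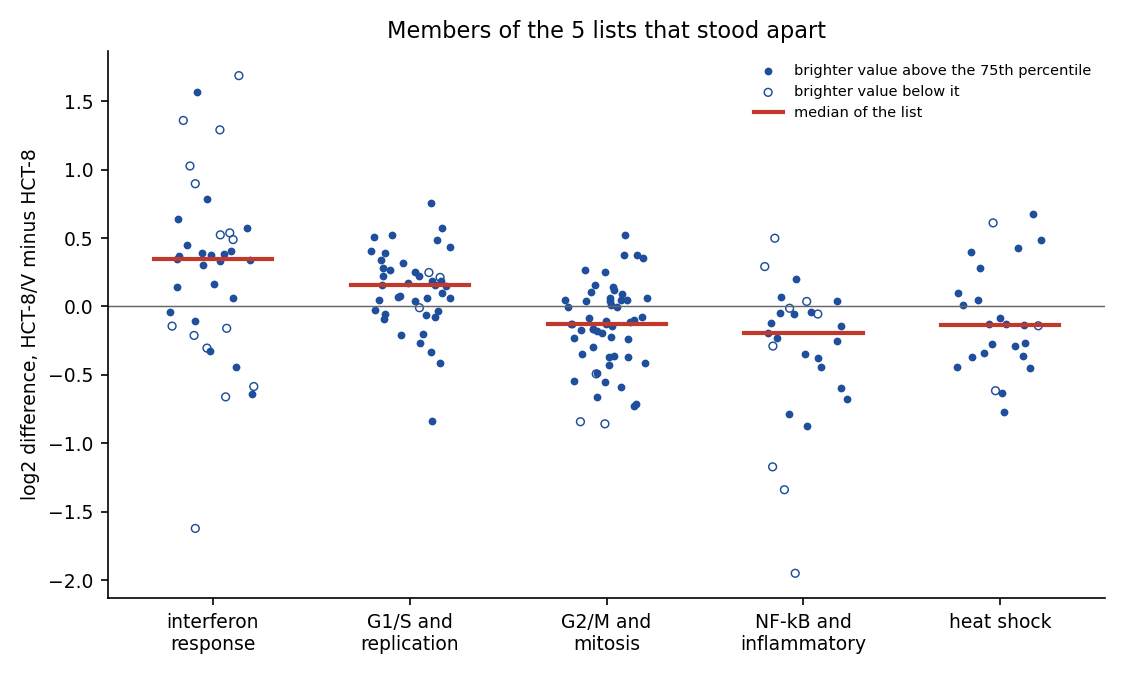
Each point is the log2 difference, HCT-8/V minus HCT-8, of 1 expressed member of the 5 lists that stood apart, and the red line is the median of the list. Filled points have a brighter value above the 75th percentile of all probes and open points below it, and the medians run from 0.34 for interferon response genes to -0.19 for NF-kB and inflammatory genes.

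The other 32 lists lay between percentiles 5.76 and 97.79. Unfolded protein response genes were the nearest to standing apart on the high side, with 21 of 29 higher, and did so at the higher floor, with all measured members and as a mean. Wnt target and stem cell genes were the nearest on the low side, with 14 of 20 lower. Proteasome genes ranked at 95.7, TGF-beta and SMAD targets at 9.37, mismatch and excision repair genes at 69.9, double-strand break repair genes at 59.0, p53 targets at 22.7, hypoxia and glycolysis genes at 69.7, oxidative phosphorylation genes at 32.2, cholesterol biosynthesis genes at 63.2, ribosomal protein genes at 26.1, growth factor receptor and RAS-MAPK feedback genes at 43.5 and cancer-testis antigen genes at 72.1. Intestinal differentiation genes ranked at 33.9. Markers of leukocytes (53.9), endothelium (74.6), neural cells (53.04) and hepatocytes (59.8) did not stand apart. Of these, 19 of 31 leukocyte, 8 of 16 endothelial, 8 of 22 neural and 10 of 19 hepatocyte markers were above the floor on at least 1 array. The albumin gene ALB read 78.1 in HCT-8 and 86.5 in HCT-8/V, the latter above the higher floor, while PTPRC (11.2 in HCT-8 and 7.10 in HCT-8/V), CDH5 (-5.23 and -15.2) and SOX10 (-2.65 and 5.78) were below the floor in both.

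**Figure D3:**
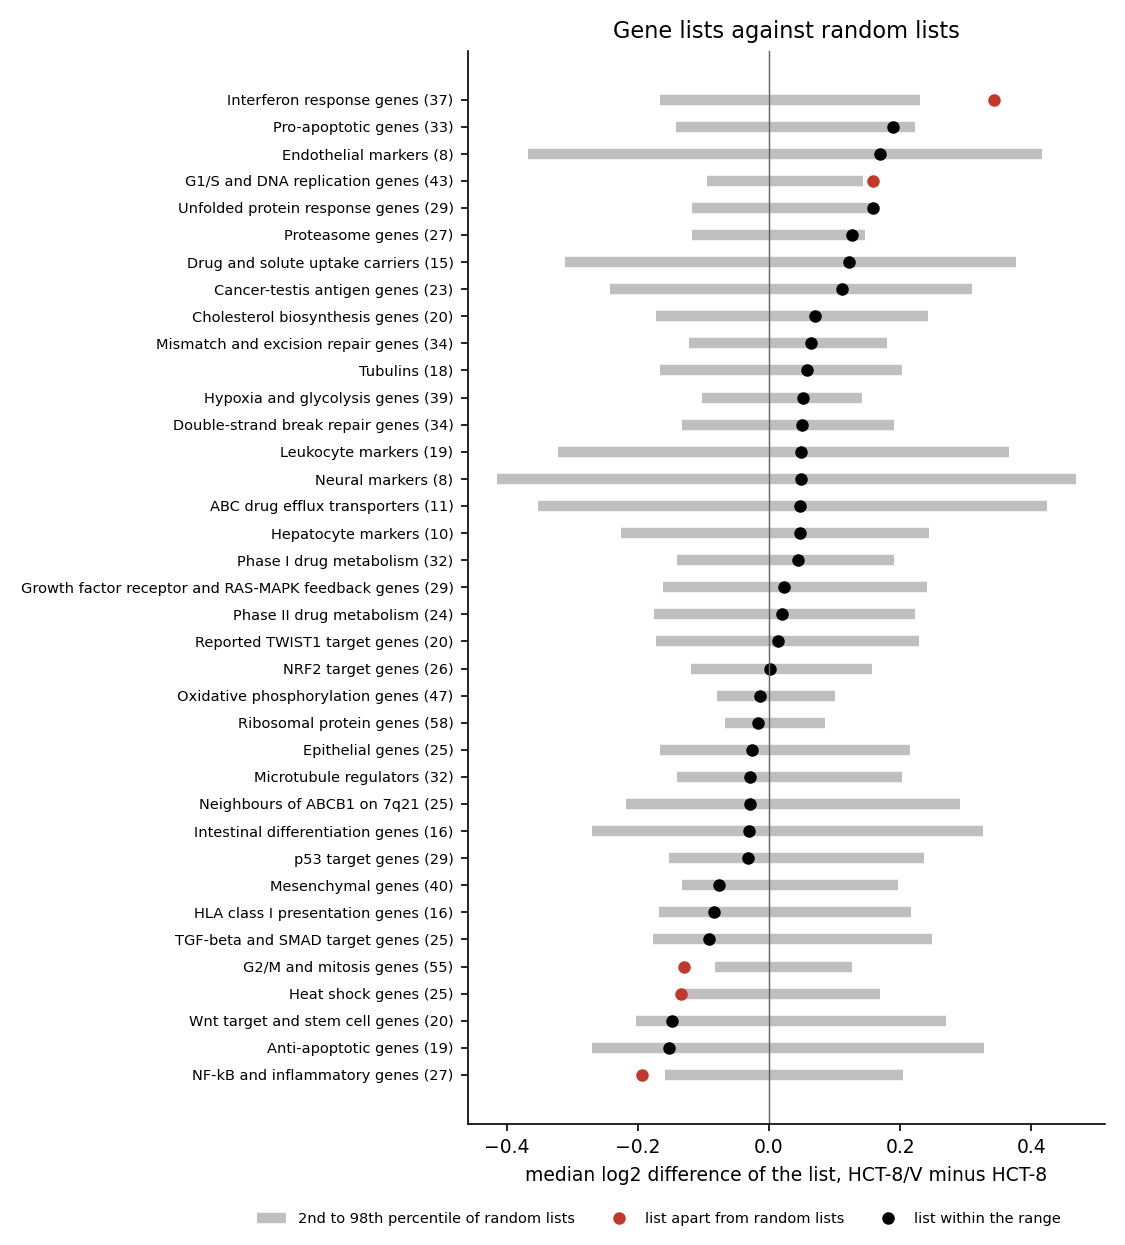
The median log2 difference, HCT-8/V minus HCT-8, of the expressed members of each of 37 lists is a point, with the number of members in parentheses, and the grey bar spans the 2nd to 98th percentile of 10000 expression-matched random lists. The 5 lists apart from random lists are red: interferon response and G1/S genes lie above, and G2/M, heat shock and NF-kB genes below.

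Over 13728 genes placed in order, 0 runs of 15 genes lay beyond the shuffled gene orders. The highest window median was 0.77, against 1.08 in shuffles, and the lowest was -0.54, against -0.96. Windows of 25 genes gave 0 runs as well. A window of 15 genes had to pass 1.08 or -0.96, so a smaller shared shift would be missed. The absence of runs therefore does not exclude a gain or loss of a region.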

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

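The tests for the same labelled RNA and of the intestinal and epithelial genes were chosen after the results were seen. The higher floor and the loess trend were fixed before the data were examined, but their use as tests of the interferon and G2/M lists was decided after the results were seen, and the second brightest probes of the lists were added after seeing the data.

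Probes without a single gene name were left out of the gene results, and they held large differences too. At the higher floor, 8 of them were at least 2-fold higher and 18 at least 2-fold lower in HCT-8/V, of 2375 such probes above that floor. ILMN_3295946 was 4.32-fold higher (211 in HCT-8 and 914 in HCT-8/V), and ILMN_1844299 was at least 4.19-fold lower (341 and 68.3, the second below the higher floor).

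The first pattern is the large number of 2-fold differences among dim genes beside the few at the higher floor. Noise was simulated as normal noise of the size seen in probes below 0 (standard deviation 7.60) plus a proportional part. The proportional part came from pairs of bright probes (standard deviation 0.258 of the log2 difference). Applied to the mean of both arrays, with means below 0 set to 0, it gave 298 to 381 genes past 2-fold in 100 simulations. The median was 31.0% of the 1102 observed, so noise of that size and shape did not account for all of them. The second probe of the same gene, however, went the same way in only 87 of 183 dim genes (47.5%, against a median of 49.7% and a highest value of 61.7% in shuffled pairs). The differences of these genes may be noise of single probes. The second probe is the dimmer of the 2, so it may also have missed a change, and the test cannot separate these. For the bright genes the second probe went the same way in 9 of 15 (60%, with a highest shuffled value of 86.7%), which is too few to tell probe noise from a change in the gene. The same labelled RNA on both arrays is argued against, since the differences of 2 probes of a gene were correlated across 1535 genes (Pearson 0.307, highest of 1000 shuffles 0.0721).

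The second pattern is the gene lists that stood apart. For interferon response genes, noise of dim probes is argued against by the percentile at the higher floor (99.98). With the loess trend removed the percentile was 99.94, but the random lists were already matched on brightness. That removal could therefore hardly change the percentile and does not test a trend with brightness. Only 8 members had a second probe, with a median of 0.40 (percentile 98.98) but a mean of 0.08 and 2 lower. That percentile met the bound set for this test, but the bound asked for no minimum number of genes. As 8 with such a spread are too few, single probes stay open. For G2/M genes, noise of dim probes is argued against by the percentile at the higher floor (0.35), but the second brightest probes of 23 members reached only 4.49, so chance differences of single probes stay open. With 1 array per line, a difference between the lines cannot be told apart from one between these cultures, such as their density or their response to the plasmid.

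The third pattern is that most genes of the intestinal list lay near background in both cultures. Of 52 measured intestinal genes 6 (11.5%) were above the higher floor, against 40.0% of all genes. The 6 were MUC13, KLF4, KLF5, ANPEP, the placental gene ALPP and its close relative ALPI. The list mixes markers of several intestinal cell types, so the share of all genes is only a loose baseline for it. Epithelial genes as a list were not short of bright members, with 17 of 43 (39.5%), among them KRT8, KRT18, JUP, DSG2, MUC1 and, in HCT-8 only, EPCAM. At the median floor, however, 25 of 43 epithelial genes were expressed, against 68.7% of all genes. CDH1, OCLN, CLDN3, CLDN4, ESRP1 and GRHL2 were below that floor in both cultures. Whether the intestinal genes were lost with TWIST1, or the cultures are of an origin other than intestinal epithelium, cannot be told apart here, because no array without the plasmid and no reference profile were analysed.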

How the results depend on the processing

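The alternatives were fixed before the data were examined, except the second brightest probes, which were chosen after seeing the data. No paired analysis was possible because each line has 1 array, and leaving out an array was impossible for the same reason. A detection p-value in place of a floor was not run, as the table gives none, and TWIST1 and ABCB1 have no count of arrays above a floor when no floor is set.

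The numbers of genes at least 2-fold higher in HCT-8/V and of genes at least 2-fold lower in HCT-8/V depended strongly on how dim values were treated, and signal over background limits them. From 583 and 519 they went to 24 and 25 with the floor at the 75th percentile, 84 and 86 with no floor and no filter, where 46.0 was added to every intensity, 375 and 329 with the mean of all probes, 85 and 74 at 3-fold, and 1760 and 1546 at 1.5-fold. Requiring 2 or more probes, all past 2-fold, left 5 and 8, chosen for naming after their values were seen: N4BP1, PALMD, TSHR, UNC119 and YJU2 were higher, and ANKH, MAFG, NBPF15, NRARP, RCAN1, TWF1, ZFP92 and ZNF48 lower. Only 3785 genes had 2 probes above the floor, and the others could not count here. The 5 and 8 are therefore not the share of the 583 and 519 that a further probe bears out. Quantile normalization, median centring and loess kept both counts within 1.5 times, but which direction had more genes depended on the scaling: 529 were higher and 573 lower with median centring, and 489 and 604 with loess. Quantile normalization could hardly change the counts, because the deposited arrays were already matched in distribution. The change with the fold threshold follows from the threshold. Raising values to the higher floor or adding 46.0 shrinks the ratios of dim genes, and 974 of the 1102 had a brighter value below that floor. How much of the drop with 2 or more probes comes from that requirement, and the cause of the other changes, were not tested.

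TWIST1 was above the floor on both arrays wherever a floor was set. ABCB1 was above it on 1 array, but on 0 with the floor at the 75th percentile. Of 59 named genes past 2-fold, 50 fell under 2-fold with no floor, 22 with the mean of all probes, and 1 each with loess and median centring, all in the same direction, as did 3 of the 6 that had a value with the floor at the 75th percentile. With the mean of all probes, 16 of the 106 genes named by the rule, all under 2-fold, moved, and 4 of them (ATP7B, SLCO2B1, MAPT and MAP2) turned direction. With no floor 18 moved, and with the floor at the 75th percentile 2 of the 34 that had a value (MAPT and CLASP2). None with a value turned direction in these or under the other scalings. Quantile normalization and median centring barely moved the values, so they could hardly have turned any. No run of neighbouring genes appeared in any setting, though a smaller shared shift of a region would be missed.

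Between 4 and 6 lists stood apart across the planned settings. The interferon list stood apart in all of them and with the second brightest probes. Quantile normalization of matched arrays, the constant shift of median centring and loess against brightness-matched random lists could hardly change a percentile. Those settings are therefore no independent checks of the lists. The G1/S median weakened to 0.11 with no floor, 0.10 with the mean of all probes and 0.12 as a mean, and was reversed, at -0.45, with the second brightest probes. With these the NF-kB median was also reversed, at 0.15 (mean -0.04), and the G2/M median, at -0.26, no longer stood apart. The heat shock list weakened to -0.10 as a mean. Beyond the 5 lists, unfolded protein response genes came to stand apart with the floor at the 75th percentile (0.15), with all measured members (0.11) and as a mean (0.17), epithelial genes with the mean of all probes (-0.21) and anti-apoptotic genes as a mean (-0.30). Apart from the G1/S, NF-kB, G2/M and heat shock changes given, the cause of which was not tested, the 5 lists kept their side.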

Other observations

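The tests of YAP target, Notch and histone genes in this part were chosen after the results were seen. The other lists given here and their planned settings were fixed before.

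Some abundant transcripts, chosen after their values were seen, were at similar levels in both cultures. The folate receptor gene FOLR1 read 16391 in HCT-8 and 14857 in HCT-8/V, the placental alkaline phosphatase gene ALPP 9837 and 10712, the urea cycle gene CPS1 6609 and 6536, the mesothelin gene MSLN 4828 and 5251, and the mucin genes MUC1 4432 and 4355 and MUC13 4281 and 3464. ALPI, the intestinal relative of ALPP with a very similar sequence, read 642 and 800. KLF4 was at 829 and 719.

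Beside these, several intestinal and epithelial genes were near background in both: CDH1, VIL1 (-20.4 and -22.8), CDX2 (5.32 and 2.13), KRT20 (-2.37 and 8.34), CEACAM5 (11.3 and -17.2), CLDN3 (-30.0 and -24.9) and ESRP1 (0.137 and 12.2). CDH17, at 66.4 and 65.6, and EPCAM, at 117 and 80.0, were above the floor. Of the mesenchymal genes, FN1, ZEB1 and SNAI1 were below the floor as well, and CDH2 was at 99.8 and 119.

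Unfolded protein response and proteasome genes were more often higher in HCT-8/V (21 of 29 and 18 of 27), and neither list stood apart (percentiles 97.79 and 95.7). The first did so at the higher floor, with all measured members and as a mean, but not with the mean of all probes, and the second in no setting. Among members chosen after their values were seen, TRIB3 read 471 in HCT-8 and 848 in HCT-8/V, CRELD2 513 and 871, DDIT3 710 and 1036, HSP90B1 4167 and 5990, and the proteasome subunit gene PSMD4 782 and 1360, while HYOU1 was lower at 669 and 576 and PSMC4 at 397 and 276.

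The low reading of CCN1, a target of the Hippo effector YAP, could come with lower YAP activity. The other 27 expressed YAP targets had a median of -0.08 (percentile 11.5), which does not decide it. The low readings of NRARP and RBPJ could come with lower Notch signalling, but the 18 other expressed genes examined, with a median of 0.12 (percentile 79.9), mix targets with receptors, ligands and antagonists of the pathway, so they do not test it. The G1/S list stood apart on the high side with the brightest probes, but its median was reversed with the second brightest (-0.45), so a difference in the share of cells in S phase has little to rest on. Replication-dependent histone genes, which peak there, had a median of -0.02 over 39 genes (percentile 25.95), but most of their transcripts lack the poly(A) tail that the labelling commonly relies on, so this test decides little.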
